A study of Xenopus tropicalis with 12 samples.

How the data were processed

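The data were 12 lists of peaks, 1 per library, from chromatin immunoprecipitation with a TR antibody and sequencing (ChIP-seq) of tadpole tail. Per the submitters' processing notes, reads were aligned with Bowtie2 2.3.4.1 and peaks called with MACS2 2.1.1.20160309. Per the file headers, MACS2 ran on paired-end fragments of each library on its own, after removal of duplicates and without an input control library, with a q-value cutoff of 0.05, an effective genome size of 1510000000 bp and a local background over 10000 bp. The genome was build 9.1 of Xenopus tropicalis, per the file headers, and all peaks lay on its 10 chromosomes. Coordinates are those of the deposited lists, counted from 1.

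The deposited lists give, for every peak, the pileup (signal: the number of fragments over the summit, not scaled to depth, per the file headers), the fold enrichment (a ratio of the pileup to the local background of the same library, with a constant added to both, computed by MACS2 for the authors), and −log10 of the p-value and of the q-value, per the file headers. Because of the constant, the fold enrichment of a peak of few fragments is far below the plain ratio and largely restates the pileup. These values are the authors' and were used to describe peaks and to rank or filter them within a list. Pileups of several libraries printed side by side are unscaled, and since depth sets how many fragments a site can have, a difference between them is not a difference in level. Scaling to depth was used to ask how many fragments a library without a peak would have had, for peaks per list, and where values are given per 1000000 fragments. Without an input library, a peak marks a place with more fragments than its surroundings and does not by itself tell antibody enrichment from a site that yields many fragments in any library.

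The labels gave genotype, treatment and a replicate number, and these set the 4 groups of 3. The series' design note speaks of RNA and of 3 technical replicates from merged tadpoles, although these libraries are ChIP DNA. It was read here as technical replicates of material pooled per group. On this reading, p-values measure the spread between libraries and not between animals. Depth was taken as the fragments after filtering in the file headers. A depth of 149532 to 1547243 fragments over a genome of this size is low, so a missing peak means that it was not called at this depth, not that the receptor was absent.

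Peaks of the 12 lists were merged into regions where they shared at least 1 bp, and each region was marked as present or absent in each list. A region was called reproducible in a group with a peak in at least 2 of its 3 lists, and exclusive to a group, against another, with a peak in all 3 lists of the first and none of the second. Association with T3 or with genotype needed a peak in at least 5 of the 6 lists of one kind and at most 1 of the 6 of the other. Numbers of peaks were compared by exact two-sided permutation tests: 20 assignments for 3 against 3 libraries (smallest p 0.1), and 400 assignments within strata for T3, genotype and their interaction (smallest p 0.005). Similarity of lists within and between groups was tested by 100000 resamples of the assignment to groups. These designs, and the rule for named regions, were fixed before the data were examined. Afterwards, 100 randomisations were added that exchanged regions between lists in 300 rounds of trades, keeping every list's length and every region's number of lists. Merging, counting and randomisation were tested on simulated lists for WT control against WT T3, over 256032 regions, in which 100.0% of 200 planted exclusive regions were recovered. Each planted region was given overlapping peaks in all 3 WT control lists and none elsewhere. Calls missed at low depth were not simulated, so this checked the computation and not how many real sites were found.

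By the rule, the text names up to 6 exclusive regions per comparison and direction, up to 6 associated regions per direction and 10 regions of all 12 lists. They were ranked by the lowest percentile that the peak's p-value score had within the lists concerned. The regions past the stricter threshold in 1 group alone and the tall regions among the observations were chosen after their values were seen. Alternatives were a stricter threshold (−log10 q of at least 5), lists of equal length (the best 13493 peaks), summits within 200 bp as the overlap, other numbers of lists, peaks per 1000000 fragments, pairing by replicate number and leaving out each library. A minimum of 3 fragments at the summit was added after the data were examined.

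Genes at the regions, the peaks near known T3 response genes and 16 fixed gene lists, the DR4 thyroid hormone response element and the location of peaks relative to genes were planned and not analysed here, because no annotation or sequence of build 9.1 was used here; the gene table at hand was of build 10.0 and its coordinates were not used. Intervals for shares are 95% Wilson intervals and cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.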

Results

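Chromatin from the tail of Xenopus tropicalis tadpoles was precipitated with an antibody against thyroid hormone receptor (TR), and the DNA that came down was sequenced to find where the receptor sat on the genome. Tadpoles around stage 54, before the climax of metamorphosis when the tail is resorbed, were either wild type (WT) or lacked both copies of the gene for TRα (KO), the more widely expressed of the paired receptors TRα and TRβ. They were left untreated (control) or kept in 10 nM T3, the active thyroid hormone, for 18 hours. Each of the 4 groups (WT control, WT T3, KO control and KO T3) had 3 libraries, 12 in all, and WT and KO tadpoles came from the same parents. The question was where TR was found in the tail, and how that differed with T3 and without TRα.

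The lists of peaks (places where sequenced fragments piled up) rested on few fragments per library. After removal of duplicates the libraries held 149532 (KO T3 3) to 1547243 (KO T3 2) fragments. The group means were 962600 ± 454509 for WT control, 534284 ± 237428 for WT T3, 583023 ± 287577 for KO control and 839030 ± 699043 for KO T3 (SD, n = 3). The lists held 13493 to 49390 peaks, with means of 33167 ± 14828, 27628 ± 12440.5, 29341 ± 13108 and 21266 ± 7611.5 in the same order. In 9 of the 12 lists the lowest peaks had 2 fragments at the summit, in WT control 3 and KO T3 2 they had 3, and in KO T3 3, the shallowest library, 49.0% of peaks had a single fragment. Peaks with at least 3 fragments rose with depth over the 12 libraries (Pearson's r = 0.898, p = 5e-05; Spearman's rho = 0.958, p = 1e-05, the smallest p that 100000 permutations can give; r = 0.949 without KO T3 2 and WT control 3). Adjusted over the 4 relations with depth that were computed, these p-values were 6.67e-05 and 2e-05. All peaks together gave r = 0.473 (p = 0.122) and rho = 0.671 (p = 0.0203) in the same permutation test, the same values after adjustment, and r = 0.941 without the same 2 libraries.

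**Figure D1:**
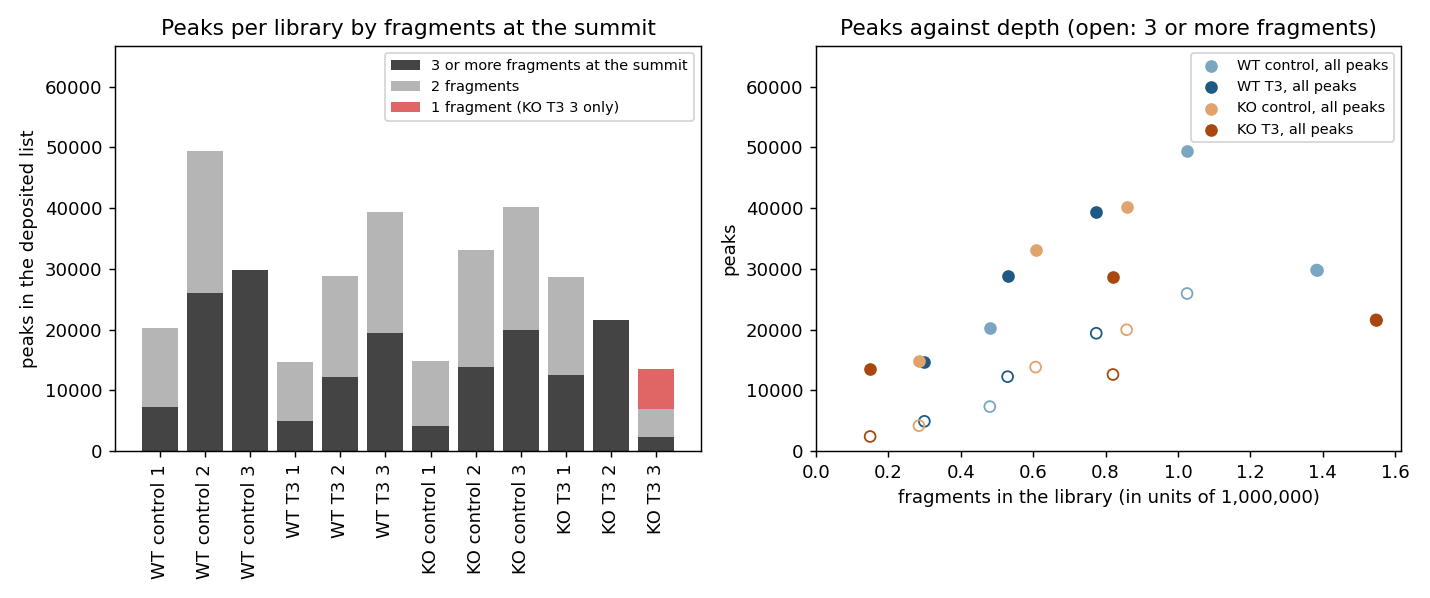
Left, number of peaks in each of the 12 lists, stacked by the fragments at the summit (1, 2, or 3 and more). Right, peaks against fragments per library (in units of 1000000), filled for all peaks and open for peaks of 3 or more fragments; WT control 3 (29795 peaks) and KO T3 2 (21600 peaks), the deepest libraries, held no peak of 2 fragments.

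A core of shared regions was found in every library, with or without T3 and with or without TRα. Without an input library, such regions are not told from sites that yield many fragments with any antibody. Peaks of the 12 lists merged into 256032 regions, and 384 of these had a peak in all 12 lists, 149 of them with at least 5 fragments at the summit in every list. The 384 became 224 when windows around summits were merged in place of peaks, and 74 of 12341 regions at the stricter threshold, where 64.1% of regions were in a single list. The highest ranked was on chromosome 8 from 23529071 to 23530254 (build 9.1), with 127 fragments at the summit in KO control 1 and 1551 in KO T3 2. A region on chromosome 5 from 35928549 to 35930448 had 150 to 1545 fragments, and a region on chromosome 10 from 16969892 to 16970788 had 124 to 1204. A further pair of strong regions lay on chromosome 8 from 23523129 to 23524073, with 92 to 873 fragments, and on chromosome 4 from 52501689 to 52502265, with 64 to 585. The other 5 of the 10 highest ranked were on chromosomes 3 (from 110350625), 5 (from 136045339 and from 145703921), 8 (from 97813504) and 9 (from 80023985). The 384 shared regions had a median of 13 fragments at the summit and a median fold enrichment, with its added constant, of 7.82, against 2 fragments and 2.81 for the 225389 regions (88.0%) seen in a single list. At so few fragments the 2 measures are not independent. Regions with a peak in at least 2 of the 3 lists of a group numbered 8314 in WT control, 5326 in WT T3, 5168 in KO control and 6221 in KO T3, and 1776 of them were common to the 4 groups.

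**Figure D2:**
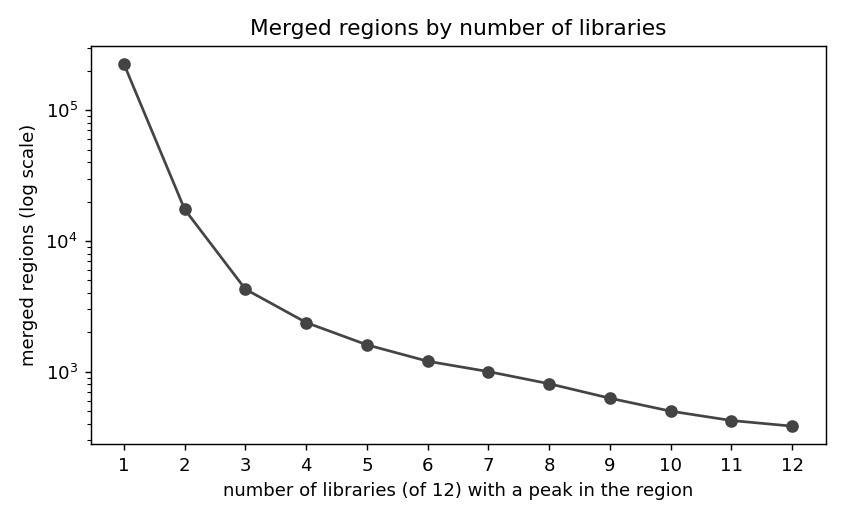
Number of merged regions (log scale) by the number of the 12 libraries with a peak there. The count goes down from 225389 regions in 1 library to 384 in all 12.

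The effect of T3 on TR at chromatin of normal tail was addressed by WT T3 against WT control. T3-treated tails had 42 regions with a peak in all 3 WT T3 lists and in no WT control list. Of these, 28 had a peak in some KO list. The highest ranked lay on chromosome 3 from 128615382 to 128615819, with 12, 12 and 22 fragments at the summit in WT T3 1, 2 and 3. It was followed by chromosome 3 from 46875486 to 46875854 (11, 9 and 14 fragments) and chromosome 6 from 94892437 to 94892792 (6, 16 and 24). A region on chromosome 7 from 78018625 to 78019062 had 6, 8 and 11 fragments, and a region on chromosome 3 from 129191256 to 129191622 had 13, 8 and 18. These 5 regions had no peak in any of the 9 other lists, KO T3 included. The region on chromosome 1 from 134958790 to 134959408 (12, 8 and 22) also had a peak of 2 fragments in KO control 3. In the other direction, 288 regions had a peak in all 3 WT control lists and in no WT T3 list, 250 of them with a peak in some KO list. The highest ranked was on chromosome 4 from 35764037 to 35764582 (9, 21 and 20 fragments in WT control, 12 in KO T3 1), followed by chromosome 8 from 97849908 to 97850635 (14, 14 and 20, with peaks in 4 KO lists). Next came chromosome 8 from 114979702 to 114980025 (7, 15 and 14), which also had 13, 30 and 8 fragments in the KO T3 lists, chromosome 2 from 144971483 to 144971817 (6, 11 and 14), and chromosome 5 from 102754223 (4, 14 and 17) and from 138070931 (4, 7 and 10). A total of 3244 regions were reproducible in both groups.

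The 42 regions were within the 35 to 68 given by 100 randomisations that kept the length of every list and the number of lists of every region, and the 288 were above their 176 to 258. At the stricter threshold the counts were 10 and 66, against 0 to 4 and 42 to 76 when randomised. The number of peaks per list differed by less than the spread between libraries (-5538, T3 minus control, exact two-sided permutation p = 0.6; 3 against 3 cannot go below 0.1), and its direction turned without WT control 2 (2573) or WT T3 1 (970.3). Per 1000000 fragments it also turned, to 14067 (p = 0.1, the smallest the exact test allows), with 48802 to 54556 in WT T3 and 21548 to 48188 in WT control. These lists had different smallest pileups. WT control 3, the lowest of them per 1000000 fragments, held no peak of 2 fragments, while 50.8% to 66.4% of peaks in the WT T3 lists had 2. Leaving out a library can only keep or raise a count of exclusive regions, here and below, since fewer lists then decide. The 42 became 670, 331 and 258 without WT T3 1, 2 or 3 and 76 and 82 without WT control 2 or 3. The 288 became 1728, 719 and 851 without WT control 1, 2 or 3 and 464 and 670 without WT T3 2 or 3.

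In tails without TRα, the same treatment gave 160 regions with a peak in all 3 KO T3 lists and in no KO control list. Of these, 148 had a peak in some WT list, so few belonged to KO T3 alone. The region on chromosome 8 from 114979702 to 114980025 ranked highest, with 13, 30 and 8 fragments in KO T3 1, 2 and 3. It was the region that WT control had and WT T3 had not. Chromosome 1 from 808758 to 809781 (10, 17 and 4 fragments), chromosome 7 from 1121935 to 1122342 (10, 13 and 6) and chromosome 1 from 190309062 to 190309580 (9, 15 and 5) also had peaks in WT lists of both treatments, as did chromosome 3 from 118704136 to 118704801 (6, 10 and 5). The region on chromosome 10 from 3435609 to 3435859 (7, 19 and 5) had a peak in KO T3 alone. Regions of KO control with no peak in KO T3 numbered 62, 41 of them with a peak in some WT list. The leading region was on chromosome 8 from 49452 to 50188, with 15, 18 and 36 fragments in KO control 1, 2 and 3. It was followed by chromosome 8 from 12127979 to 12128250 (23, 17 and 35), chromosome 4 from 109908964 to 109909301 (12, 24 and 16) and chromosome 2 from 81772517 to 81772988 (13, 15 and 25). The remaining pair was on chromosome 7 from 52189922 (8, 12 and 33) and chromosome 2 from 2374758 to 2375404 (9, 21 and 23). Both KO groups shared 2693 reproducible regions.

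Of these counts, 160 was above the 78 to 124 of the 100 randomisations and 62 was within their 59 to 99. At the stricter threshold both counts were 22, against 3 to 20 and 0 to 5 when randomised. Peaks per list differed by -8075 between KO T3 and KO control (exact two-sided permutation p = 0.4), with the opposite sign, 745 (p = 0.7, same test), at the stricter threshold. Leaving out KO T3 1, 2 or 3 changed the 160 to 508, 393 and 1128, and leaving out KO control 2 or 3 to 269 and 336. The 62 became 951, 336 and 245 without KO control 1, 2 or 3 and 94 and 153 without KO T3 1 or 2.

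Untreated tails with and without TRα were compared to see what the loss of this receptor changed in the absence of added hormone. WT control had 343 regions, present in all 3 lists, that no KO control list had. Of these, 305 had a peak in some T3 list. The highest ranked was on chromosome 2 from 83370793 to 83371152, with 67, 61 and 66 fragments in the WT control lists, 2 and 5 in WT T3 2 and 3 and 1 in KO T3 3. Chromosome 9 from 67958300 to 67958705 had 12, 23 and 25 fragments in WT control, 16 and 14 in WT T3 1 and 3, and 16 in KO T3 1. The others named by the rule were the regions on chromosome 4 from 35764037 and chromosome 8 from 114979702 given above, chromosome 1 from 10109862 to 10110499 (10, 17 and 32) and chromosome 3 from 136789180 to 136789610 (10, 13 and 13). KO control had 53 regions that no WT control list had, 32 of them with a peak in some T3 list, led by chromosome 7 from 12447957 to 12448215 with 34, 67 and 72 fragments, and 25 and 9 in KO T3 2 and 3. The 4 regions on chromosome 8 from 49452, chromosome 4 from 109908964 and chromosome 2 from 81772517 and from 2374758, given above, were in KO control and in none of the 9 other lists. The last, on chromosome 8 from 15001597 to 15001807 (14, 12 and 12), had 10 fragments in KO T3 2. Reproducible regions common to WT control and KO control numbered 3013.

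The 343 exceeded the 192 to 261 of the randomisations and the 53 was within their 31 to 67, and at the stricter threshold the counts were 93 and 20 against 45 to 85 and 0 to 3. Peaks per list differed by -3826 (KO minus WT, exact two-sided permutation p = 0.8), with the opposite sign without WT control 2 (4286) or KO control 1 (3468) and per 1000000 fragments (13743, p = 0.2 in the same test). Without WT control 1, 2 or 3 the 343 became 1842, 777 and 953, and without KO control 2 or 3 it became 566 and 720. The 53 became 846, 302 and 233 without KO control 1, 2 or 3, and 100 and 110.0 without WT control 2 or 3.

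The same comparison after T3 asked what the loss of TRα changed in the presence of hormone. KO T3 had 130 regions that no WT T3 list had, 118 of them with a peak in some control list. Beside the regions on chromosome 8 from 114979702 and chromosome 10 from 3435609, the rule named chromosome 3 from 128902298 to 128903033 (7, 18 and 4 fragments), chromosome 4 from 5806860 to 5807623 (5, 14 and 4), chromosome 3 from 3155527 to 3156169 (9, 10 and 3) and chromosome 5 from 4497923 to 4498484 (7, 11 and 3). WT T3 had 80 regions that no KO T3 list had, 66 of them with a peak in some control list. Among them were the regions on chromosome 3 from 128615382 and from 46875486 and on chromosome 6 from 94892437, which only the WT T3 lists had. Chromosome 1 from 81087438 to 81087929 (18, 13 and 12 fragments), chromosome 7 from 17658664 to 17659177 (6, 11 and 13) and chromosome 7 from 95759216 to 95759565 (6, 12 and 12) had peaks in WT lists of both treatments and in no KO list. Both T3 groups shared 2841 reproducible regions.

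Here 130 was above the 70 to 126 of the randomisations and 80 was within their 63 to 113. At the stricter threshold the counts were 9 and 15, against 1 to 15 and 0 to 6. Peaks per list differed by -6362 (KO minus WT, exact two-sided permutation p = 0.4) and, with the opposite sign, by 19 (p = 1) with at least 3 fragments at the summit and 620 (p = 0.7) at the stricter threshold, in the same test. The 130 became 451, 351 and 1039 without KO T3 1, 2 or 3 and 223 and 320 without WT T3 2 or 3. The 80 became 847, 399 and 317 without WT T3 1, 2 or 3 and 203 without KO T3 2.

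**Figure D3:**
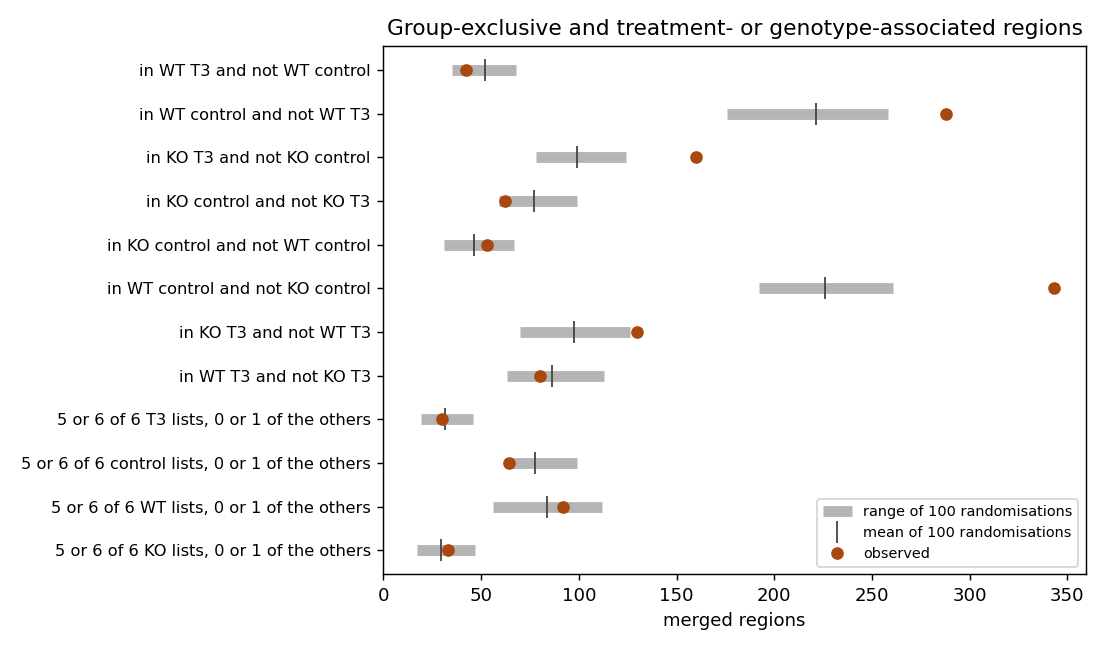
Number of merged regions exclusive to a group in each comparison (upper 8 lines), and associated with a treatment or a genotype (lower 4 lines). Dots are the observed counts; bars are the range and ticks the mean of 100 randomisations. Observed counts lie right of the bar for WT control in both its comparisons (288 and 343) and for KO T3 in both of its own (160 and 130).

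Over both genotypes, few regions followed T3. A peak in at least 5 of the 6 T3 lists and at most 1 of the 6 control lists was found in 30 regions, and the reverse in 64. The T3-associated regions were weak, such as chromosome 5 from 3984074 to 3985176 with 3, 4 and 4 fragments in WT T3 and 9 and 8 in KO T3 1 and 2, and chromosome 9 from 29572793 to 29573050 with 7 and 7 in WT T3 2 and 3 and 13, 7 and 3 in KO T3. The control-associated regions were led by chromosome 4 from 4488438 to 4489737, with 6, 16 and 21 fragments in WT control. It had 8 and 9 in KO control 2 and 3 and 11 in WT T3 3. The tallest of the 6 highest ranked, at rank 4, was on chromosome 1 from 72744074 to 72744327. It had 8, 23 and 28 fragments in KO control and 4 and 12 in WT control 2 and 3. Both counts were within the randomised ranges of 19 to 46 and 62 to 99. Leaving out 1 library gave 36 to 117 and 67 to 243, highest without WT T3 1 and KO control 1. The number of peaks differed by -6807 (T3 minus control, exact permutation within genotype, two-sided p = 0.31), and by 4686 peaks per 1000000 fragments.

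Over both treatments, 92 regions went with the presence of TRα and 33 with its absence. The WT-associated regions were led by chromosome 9 from 67958300 and chromosome 7 from 95759216, already described, and by chromosome 8 from 98698827 to 98699783 (7, 15 and 16 fragments in WT control, 14 and 22 in WT T3 2 and 3, and 2 in KO T3 3). The KO-associated regions included the tallest of these sets, on chromosome 1 from 71652839 to 71653056, with 113, 218 and 232 fragments in KO control, 71 and 36 in KO T3 2 and 3, none called in KO T3 1 and 13 in WT control 1. It was followed by chromosome 7 from 12447957 and by weaker regions on chromosome 3 from 65990077 to 65990351 (5, 6 and 8 in KO control, 11 and 3 in KO T3 2 and 3), chromosome 4 from 122879684 and chromosome 1 from 189160991. Both counts lay within the randomised 56 to 112 and 17 to 47, and at the stricter threshold they were 13 and 7 against 4 to 21 and 0 to 5. Leaving out 1 library gave 102 to 316 and 43 to 118, highest without WT T3 1 and KO T3 3. The number of peaks differed by -5094 (KO minus WT, exact permutation within treatment, two-sided p = 0.465), and by 4361 peaks per 1000000 fragments.

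The difference between the T3 effects of the 2 genotypes was 2536 peaks per list (exact permutation, two-sided p = 0.845), with the opposite sign at the stricter threshold (-2399), with at least 3 fragments at the summit (-8375) and without WT control 1 (-3890), WT T3 3 (-3348.5), KO control 3 (-2857) or KO T3 3 (-1350.2). By the Jaccard index, the share of regions common to a pair of lists, lists of the same group were not shown to be more alike than lists of different groups: 0.0627 within and 0.0621 between groups (difference 0.000586, one-sided permutation p = 0.339). The difference was -0.00527 at the stricter threshold and -0.00457 with at least 3 fragments. It kept its sign with lists of equal length (0.00114) and with windows around summits (0.000797). This index followed depth: over the 12 libraries, the median index of a library with the others had r = 0.943 (permutation p = 1e-05, adjusted 2e-05) and rho = 0.916 (p = 9e-05, adjusted 0.00012) with its fragments, and r = 0.848 without KO T3 2 and WT control 3. Relative to what list lengths and region totals give, pairs of the same group shared 0.991 of the randomised number and pairs of different groups 0.967. The difference was 0.0233 (one-sided permutation p = 0.00159), in a comparison chosen after the data were examined. It was 0.0223 with at least 3 fragments (one-sided permutation p = 0.00108) and 0.0220 with lists of equal length (one-sided permutation p = 0.00189). At the stricter threshold the ratios were 1.03 and 0.974, a difference of 0.0592 (one-sided permutation p = 0.00162). These settings share the same libraries and are not independent. In the main setting the ratio varied far more between pairs than between the 2 kinds of pair. It ran from 0.746 for KO control 1 and KO T3 3, the shallowest pair, to 1.27 for WT control 3 and KO T3 2. The latter was the deepest pair and of different groups.

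**Figure D4:**
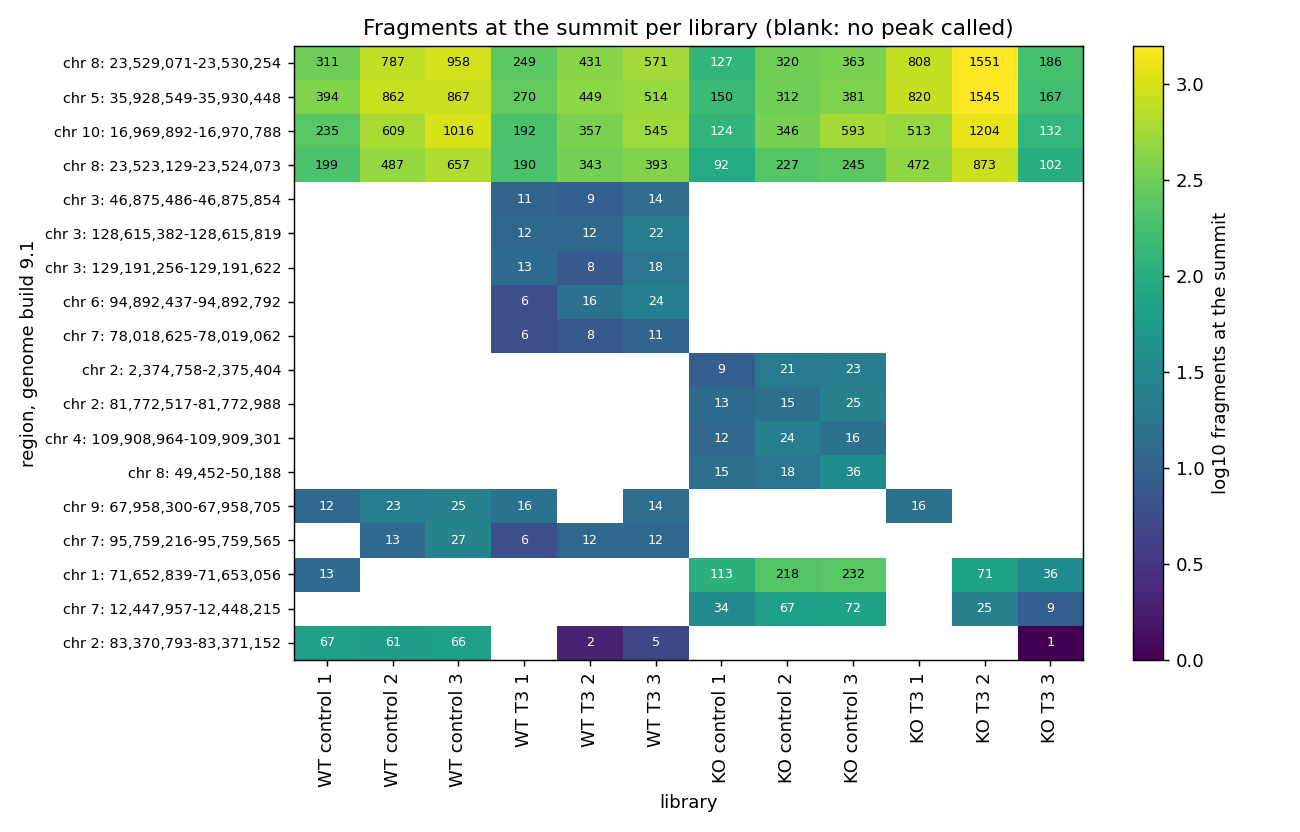
Fragments at the summit (number and colour, log scale) in each of the 12 libraries, for regions named in the text by chromosome, start and end; blank cells have no peak. From the top, 4 regions of all 12 libraries, 5 of WT T3 alone, 4 of KO control alone, 2 WT-associated, 2 KO-associated and the highest ranked region of WT control that KO control lacked.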

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

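The number of peaks in a list depended on depth and on the smallest pileup that passed, so counts of regions moved with nearly every setting, while the T3 effect, the genotype effect and the interaction in peak numbers did not pass their tests under any of them. The comparisons of 3 against 3 libraries could not pass, since their smallest p is 0.1, which WT T3 minus WT control reached per 1000000 fragments. Peaks per 1000000 fragments set lists with different smallest pileups side by side. The minimum of 3 fragments at the summit was chosen after the data were examined. Merging windows around summits within 200 bp kept 17 results within 1.5 times or in their direction, but gave 224 regions common to all 12 lists in place of 384, a count that was 283 with at least 3 fragments, 341 with lists of equal length and 74 at the stricter threshold. A setting of chromosomes alone was not run because all peaks were on the 10 chromosomes, and the planned results on known T3 genes, gene lists, the DR4 motif and genomic location, with their alternatives, were not run for want of an annotation or sequence of build 9.1. Where counts moved with fewer libraries, fewer peaks or another number of lists, the alternative's own construction changes how many regions can pass; for the reversed differences the cause was not tested.

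At the stricter threshold, reproducible regions were 1987 in WT control, 892 in WT T3, 821 in KO control and 1439 in KO T3. Exclusive regions were 10 in WT T3 and 66 in WT control against each other, 22 in KO T3 and 22 in KO control, 20 in KO control and 93 in WT control, and 9 in KO T3 and 15 in WT T3. Regions associated with T3, control, WT and KO were 3, 7, 13 and 7. Peak numbers reversed to 745 (KO T3 minus KO control), 620 (KO T3 minus WT T3) and -2399 (interaction, exact permutation p = 0.235), and the difference in Jaccard index to -0.00527.

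With at least 3 fragments at the summit, 12 results kept their direction or stayed within 1.5 times, among them KO T3 minus KO control at -459 peaks and WT T3 minus WT control at -8834. KO control had 3404 reproducible regions. Exclusive regions were 23 in WT T3 against WT control, 60 in KO T3 against KO control, and 63 in KO T3 and 46 in WT T3 against each other; associated regions were 7 (T3), 38 (control), 60 (WT) and 16 (KO). KO T3 minus WT T3 reversed to 19 peaks, the interaction to -8375 (exact permutation p = 0.435) and the Jaccard difference to -0.00457.

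With lists of equal length, reproducible regions were 5130 (WT control), 3497 (WT T3) and 3319 (KO control). Exclusive regions were 177 in WT control against WT T3, 41 in KO control against KO T3 and 214 in WT control against KO control; 33 were associated with control and 56 with WT. Asking for 3 of 3 lists left 2756, 1397, 1305 and 1616 reproducible regions in WT control, WT T3, KO control and KO T3. Asking for 6 of 6 lists against 0 left 0 regions for T3, 0 for control, 4 for WT and 0 for KO. With at least 2 of 3 lists against 0 of 3, exclusive regions were 1175 in WT T3 and 2722 in WT control, 1709 in KO T3 and 1408 in KO control, 1275 in KO control and 2886 in WT control, and 1581 in KO T3 and 1403 in WT T3. Per 1000000 fragments, differences in peaks reversed to 14067 (WT T3 minus WT control, exact permutation p = 0.1), 13743 (KO control minus WT control), 4686 (T3) and 4361 (genotype).

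Presence of regions around the group mean had r from -0.0337 to 0.0237 for same-numbered libraries of different groups and from -0.0416 to 0.0356 for differently numbered ones. The main tests did not pair the samples by number. Regions of a single list, 88.0% of all, hold these values near 0. They could thus not show whether the number marks a shared preparation. Fragment length went with the number in 11 of the 12 libraries: fragments were 151 to 171 bp long in the libraries numbered 1, 179 to 191 bp in those numbered 2, and 201 to 209 bp in those numbered 3 except KO T3 3, which had 142 bp. The index in the library names in the file headers ran from 9 to 12 in those numbered 1 and again in those numbered 2, with the groups in the same order. In those numbered 3 it ran from 21 to 24. The number may thus mark a batch, which only the replicate block takes into account. With the replicate block, 3 regions were gained and 20 lost with T3 in at least 5 of 6 pairs, 33 went with WT and 8 with KO; differences in peaks stayed by construction, such as -6807 for T3 (exact sign-flip p = 0.344), and no call changed.

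With 1 library left out at a time, reproducible regions ranged from 3646 to 8314 (WT control), 1948 to 5326 (WT T3), 1741 to 5168 (KO control) and 1989 to 6221 (KO T3). Exclusive regions ranged from 42 to 670 (WT T3) and 288 to 1728 (WT control), 160 to 1128 (KO T3) and 62 to 951 (KO control), 53 to 846 (KO control) and 343 to 1842 (WT control), and 130 to 1039 (KO T3) and 80 to 847 (WT T3). Associated regions ranged from 36 to 117 (T3), 67 to 243 (control), 102 to 316 (WT) and 43 to 118 (KO). Differences in peaks ranged from -11964 to 2573 (WT T3 minus WT control), -15369 to -2682 (KO T3 minus KO control), -10252 to 4286 (KO minus WT control), -12871 to -477.5 (KO T3 minus WT T3), -10454 to -2751 (T3), -8348.5 to -1038 (genotype) and -3890 to 10648 (interaction). The Jaccard difference ranged from -0.00306 to 0.00353.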

Other observations

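Regions that many libraries shared lay toward the ends of the chromosomes. The outer 10% of the length at either end held 19.6% (95% interval 19.4 to 19.7) of regions seen in a single list, 37.2% (36.6 to 37.8) of those in 2 or 3, 62.6% (61.3 to 63.8) of those in 4 to 7, 68.0% (66.1 to 69.9) of those in 8 to 11 and 66.9% (62.1 to 71.4) of those in all 12. Within each library, 60.4% ± 3.81 of peaks past the stricter threshold were there, against 28.8% ± 3.52 of its other peaks, a difference of 31.5 ± 3.31 percentage points (SD, n = 12) that had the same sign in 12 of 12 lists (exact sign-flip permutation p = 0.000488). Chromosome 10 carried the most regions common to all 12 lists for its length, 8.76 per 10 Mb, and chromosome 1 the fewest, 1.85, while regions of a single list were spread evenly, at 1722 to 1829 per 10 Mb on the 10 chromosomes. Shared regions were also longer, with a median peak of 668 bp in all 12 lists against 226 bp in a single list. These positions were looked at after the data were examined.

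Some tall, short regions were prominent in KO control. The region on chromosome 1 from 71652839 had 113, 218 and 232 fragments at the summit there, which is 270.4 to 397.4 per 1000000 fragments of the library. KO T3 3 had 240.8 and KO T3 2 had 45.9 on this scale. Chromosome 3 from 53245461 to 53245707 had 64, 134 and 172 fragments in KO control 1, 2 and 3, and peaks in WT control 2 (34), WT T3 1 (9) and KO T3 1 (15). Chromosome 4 from 114925038 to 114925303 had 49, 95 and 134, with peaks in 5 other lists. In WT control 1, 2 and 3, which held 480140, 1024937 and 1382723 fragments, the region on chromosome 2 from 83370793 had 67, 61 and 66 fragments at the summit, and chromosome 3 from 76367298 to 76367904 had 67, 56 and 70. The latter also had 3 and 4 in WT T3 1 and 2, 2 in KO control 1 and 9 in KO T3 3. As KO T3 3 held only 149532 fragments, its 9 do not show a lower level than in WT control. The region on chromosome 5 from 90893591 to 90894224 had a peak in all WT and KO T3 lists, with 5 fragments in KO control 1 and no peak in KO control 2 and 3. Pileups are unscaled except where stated, and none of these differences was tested.

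The tests reported in the rest of this part were chosen after the result was seen, except the splits for the associated regions, the test of other triples among regions of WT control and KO T3, and the test of position among the 9 regions.

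Chance could not be excluded for the regions associated with T3 or with genotype. For T3, 61 of 100 splits that exchanged labels within genotype gave as many regions in both directions together (94 in the real split, 693 in the highest other). For genotype, 43 of 100 splits within treatment did (125 and 693). The 10 splits of 6 libraries are too few for a share under 0.05. WT T3 and WT control gave 330 exclusive regions in both directions together (highest other 685, and 3 splits as large, the real one included). KO T3 and KO control gave 222 (623, 4 splits), KO control and WT control 396 (703, 3 splits), and KO T3 and WT T3 210 (598, 4 splits). Each of these highest splits put the 3 shallowest of the 6 libraries on one side and the 3 deepest on the other, which points to depth as a structure of the samples.

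The first pattern weighed was that WT control and KO T3 had more exclusive regions than the randomisations gave, a pattern particular to these groups only among all peaks: KO control was above its ranges at the stricter threshold (22 against 0 to 5, and 20 against 0 to 3) and with at least 3 fragments (47 against 11 to 32, and 36 against 4 to 21), by larger ratios to the randomised means there (2.04 and 3.07) than WT control (1.33) or KO T3 (1.41) against KO control, and WT T3 was above at the stricter threshold (10 against 0 to 4, and 15 against 0 to 6) and, against KO T3, with lists of equal length (60 against 23 to 57). Against KO control, the 2 counts lay above the highest randomised count under all 4 settings run (8 of 8). This argues against list lengths and how often each region is called as the whole source. For KO T3 the margin was small outside the main setting. It had 165 against a highest of 162 with lists of equal length, and 22 against 20 at the stricter threshold. With at least 3 fragments at the summit both counts lay above (2 of 2), KO T3 with 60 against 56. This argues against peaks of 1 or 2 fragments as the source of these 2 excesses, not for an excess in these groups alone. Against WT T3 only 3 of 8 did, none of them with lists of equal length (177 in 126 to 183, and 147 in 92 to 157), and 1 of 2 with at least 3 fragments, so for these counts list lengths and peaks of 1 or 2 fragments stay open. Relations between lists other than the groups stay open. Of the 72 other triples of libraries, 9.72% reached a ratio to the randomised mean as high as the lowest of the 4. The highest was 1.51 for KO T3 1, KO T3 2 and KO control 3, the deepest of the KO libraries. Every other triple held 2 libraries of 1 group and 1 of another, so its ratio can carry the relations within that group. This share can thus not tell such relations from those of the groups. Depth stays open too, since the randomisations kept list lengths and not depth. Treatment and genotype stay open as well and were not separated from these relations or from depth.

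The second was a set of 9 regions past the stricter threshold in all 3 libraries of a group and in no other list: 5 in WT T3 and 4 in KO control, the regions named for these groups above, and 0 in WT control and KO T3. Relations between lists other than the groups did give such regions, 24 over 18 of the 216 other triples of lists and at most 3 in any, but only 14 of the 15400 divisions of the 12 lists into 4 sets of 3 held 9 or more (0.0909%, the real one included), which argues against them as the whole source. Every division that kept the WT T3 lists together and the KO control lists together contained the same 9 regions, the highest other, with 12, among them. The share thus rests largely on the 2 groups that prompted it. Depth of the libraries without the peak is argued against too, since the deepest of them would have had a median of 31.0 fragments there, 22.0 at the lowest. Of the 9 regions 44.4% (18.9 to 73.3) lay within the outer 10% at either end, which leaves open whether they are sites of the same kind as those shared by all 12 lists (66.9%; Fisher's exact p = 0.17). Material pooled once per group could also give each group its own regions and cannot be told apart from an effect of T3 or of TRα: by a looser rule (past the stricter threshold in at least 2 of 3 libraries of both groups, no peak in the other groups), pairs of groups with nothing in common shared 3 regions, pairs of 1 genotype 3 and pairs of 1 treatment 0.

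The third was the tallest peak of KO control 1, on chromosome 3 from 131794174 to 131794350. It had 311 fragments in WT control 1, 209 in WT T3 1, 728 in KO control 1, 360 in KO T3 1 and 261 in KO T3 3, and no peak in the 7 other lists, so it followed neither treatment nor genotype. A preparation shared by the libraries numbered 1 stays open: KO T3 3, a single library, had 261 fragments, and its fragments were as short as theirs (142 bp). The index in its name in the file headers, 24, belongs to the 21 to 24 of the libraries numbered 3. The libraries numbered 1 and those numbered 2 both had 9 to 12, so this index alone does not tell those numbered 1 from those numbered 2. Fragment length of the library is a candidate source: the 5 lists with the peak were those with the shortest fragments, 142 to 171 bp against 179 to 209 bp (exact one-sided permutation p = 0.00126, the smallest that the 792 choices of 5 lists allow). Among tall regions not shared by all 12 lists, 7 others were at most 200 bp long. Of their 24 peaks, 75.0% were in these 5 lists, against 34.8% for longer tall regions. This lean cannot count as support, since a called peak is about as long as the library's fragments or longer. A limit of 200 bp left out in advance WT control 3, WT T3 3 and KO control 3, with fragments of 201 to 209 bp. No biological explanation was tested, since the 5 lists include all 4 groups.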
